A study of Rattus norvegicus with 20 samples.

How the data were processed

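The samples were 20 total RNA preparations of rat dorsal root ganglia, each read on 1 Affymetrix rat genome array and grouped by surgery and day after it as the labels give them. The values are intensity as deposited by the authors on a linear scale, with 1 column per sample and 8799 probe sets, and about 3 in 10 values are below 0. Array medians ran from 43.2 to 76.5, the highest being CCI 21-day replicate 1, and lay at 58.7 and 59.3 on the Seltzer 50-day arrays. Whether and how the arrays were brought to a common level, the software, and the background step are not given in the sources used here. The 59 array control probe sets were left out of the tests, which left 8740, and the GAPDH controls among them were used for array quality.

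Values below 0 were set to 0, 16 was added, and the log2 was taken. A mean was fitted for each of the 8 groups with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with statmod 1.5.0, so all groups shared 1 estimate of the spread with 12 residual degrees of freedom. Contrasts were CCI minus sham and Seltzer minus sham at each day and as means over days, CCI minus Seltzer as the mean over 14 and 21 days, the CCI effect at 21 minus 14 days, and F tests of the Seltzer effect and of sham over 14, 21 and 50 days. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 8740 probe sets of each contrast, and the threshold was 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

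A probe set counted as above background on an array when its value exceeded the 95th percentile of the size of that array's negative values. Where the dimmer group was above background on none of its arrays, the fold is a lower bound, the geometric mean of the brighter group over the background level of the dimmer group, and is written "at least". Otherwise it is the ratio of geometric mean intensities, averaged over days on the log2 scale. No fold is given where both groups were below background at a day in the contrast or where the bound fell under 1. Log2 changes of probe sets near background depend on the number added.

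Gene symbols came from the platform's probe table, updated by Entrez ID to the current rat annotation. Of the probe sets tested, 7006 had 1 symbol (6985 found in that annotation and 21 not), 308 had several and 1426 had none. Positions in the genome are not reported here. For gene lists, each of 4736 genes was represented by its probe set with the highest mean. Of 37 lists written from general knowledge, 36 had at least 5 genes measured and were tested with camera at a preset correlation of 0.01, adjusted over the lists of each contrast. Estimated correlations, the rotation test fry, and the median over a gene's probe sets were the alternatives. Lists overlap: 3 genes were in both the axotomy and the neuropeptide list, and 3 in both the antigen presentation and the interferon list.

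The genes named were chosen by a rule fixed, with the contrasts, lists and first set of alternatives, before the data were examined. For each mean contrast it names the 8 genes with the largest rise and the 8 with the largest fall among probe sets past the threshold whose single-day effects share a sign, with 1 probe set per gene and probe sets of no gene or several genes left out. It adds up to 4 members with the largest change for each list described, the 5 genes with the smallest adjusted p of each F test, and a fixed set of genes always reported where the probe table names them. An item of that set is not reported here. Members that complete a count of 5 or fewer, the members of larger counts, and Hspb1, Timp1, Rps16, Elavl4, Adcyap1, Ifitm3, Lgals3bp, RT1-Bb and RT1-CE12 where the rule does not name them, were chosen after their values were seen.

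That first set held a pseudocount of 1 or 64, quantile normalization, arrays centred on their median, the dimmest 33.3% of probe sets left out, only the groups compared, the replicate number as a block, eBayes with trend and robust settings, array weights, and each array left out in turn. The labels of 3 CCI arrays give the replicate number as a lot batch without saying of what, and the other labels do not. Deviations from the group means correlated at 0.333, 0.246 and 0.125 between the Seltzer and sham arrays of the same number at 21 days. All 3 pairs lie over 0.1, so the numbers pair those arrays by their values. No other groups compared with 3 numbers had every pair over 0.1, the nearest being CCI and sham at 21 days (0.0584, 0.0989 and 0.101). The block adds the same shift for a replicate number in every group, so it does not model pairs found at 21 days alone. Where leaving out an array left 1 in its group, that array is assumed to vary like the other groups. Chosen after seeing the data were a floor at 200, the 21-day replicate 1 arrays left out together, the 50-day arrays left out, the 21-day sham arrays as control of both CCI groups, and the 14-day arrays left out of CCI against Seltzer. The fit was tested on simulated data, 10 simulations of 8740 probe sets with 200 changed in each, whose result is given with the effect of the processing.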

Results

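Gene expression was measured in dorsal root ganglia, which hold the cell bodies of sensory neurons, taken from the injured side of rats with a sciatic nerve injury and from sham-operated rats. The nerve had been loosely tied in the chronic constriction injury (CCI) model or partly injured in the Seltzer model, whose samples the labels describe as nerve transection surgery. Total RNA of each sample was read on 1 Affymetrix rat genome array, and 20 arrays fell into 8 groups. CCI ganglia were collected at 14 days (n = 3) and 21 days (n = 3). Seltzer ganglia were collected at 14 days (n = 2), 21 days (n = 3) and 50 days (n = 2). Sham ganglia were collected at 14 days (n = 2), 21 days (n = 3) and 50 days (n = 2). The series set both pain models against sham surgery, so the comparisons were each model against sham of the same day, the models against each other, and each over time. Group values are deposited intensities, given as mean ± SD, and changes are differences of log2 values with the standard error (SE) and a limma p-value adjusted over 8740 probe sets.

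The labels do not say that the samples of a group came from separate animals, so the p-values measure a spread that may be technical. The arrays had median intensities between 43.2 and 76.5, and the number of arrays per group limits the precision of every value below. An array's background level was taken as the 95th percentile of the size of its negative values. This level lay between 169 and 326 on 17 arrays, at 499 on CCI 21-day replicate 1, and at 599 and 766 on the Seltzer 50-day arrays. Probe sets above it made up 16% to 25.8% of the total on those 17 arrays, 12.8% on CCI 21-day replicate 1, and 8.92% and 11.0% on the Seltzer 50-day arrays. The ratio of the GAPDH control signals for the 3' end and the middle of the transcript grows as RNA is degraded or copied incompletely. It was 5.10 and 8.89 on the Seltzer 50-day arrays and at most 2.85 on the others. On those 50-day arrays the middle signals, 198 and 120, lay below the background level, so the ratios are not exact. Their 5' signals were 781 and 920 and their 3' signals 1011 and 1066. On the sham 50-day arrays these lay further apart (438 and 505 against 1543 and 1480). The actin 3' to 5' ratios were 3.94 and 9.88 on the Seltzer 50-day arrays, against at most 2.40 on the others. No pair of arrays held identical values, and Pearson's r between arrays, across probe sets, ran from 0.664 to 0.965.

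**Figure D1:**
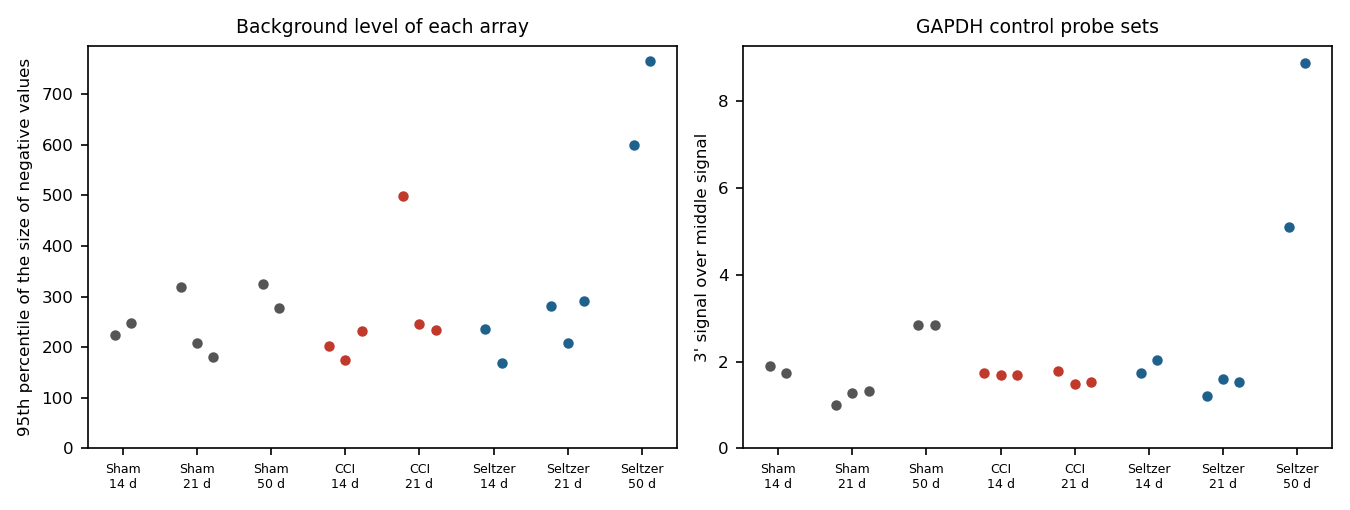
Background level of each array (intensity) and ratio of the GAPDH 3' to middle control signal, by group, with 1 point per array. The Seltzer 50-day arrays have the highest background levels, 599 and 766, and the highest ratios, 5.10 and 8.89.

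After CCI, ganglia carried far more mRNA for the neuropeptides Npy (neuropeptide Y) and Gal (galanin), which sensory neurons make little of until their axons are cut, than sham ganglia of the same day. Npy rose by 6.04 (SE 0.40, adjusted p = 1.8e-06) on the log2 scale over 14 and 21 days, at least 10.6-fold. Its intensity went from 35.5 ± 15.0 (n = 2) to 2733 ± 148 (n = 3) at 14 days and from 15.1 ± 41.4 (n = 3) to 2234 ± 350 (n = 3) at 21 days. Gal rose by 4.48 (SE 0.41, adjusted p = 3.89e-05), at least 5.86-fold. Atf3, a transcription factor induced by axon injury, rose by 2.28 (SE 0.11, adjusted p = 2.06e-07), at least 3.63-fold. Cacna2d1, the calcium channel subunit to which gabapentin binds, rose by 2.08 (SE 0.11, adjusted p = 2.06e-07), 4.29-fold. The sodium channels of nociceptors Scn10a and Scn11a fell by 1.06 (SE 0.18, adjusted p = 0.00479) and by 1.11 (SE 0.15, adjusted p = 0.000958), both 2.2-fold lower. Each of these genes moved in its direction on 6 of 6 CCI arrays, relative to the sham mean of the same day.

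Gap43, a protein of growing axons, rose by 1.24 (adjusted p = 0.00264), 2.38-fold, and Vip, another neuropeptide, rose by 2.01 (adjusted p = 0.0027) with both groups below background. The other largest rises were those of Cd74, the invariant chain of MHC class II (3.35, adjusted p = 0.00418, at least 3.59-fold) and Gfra1, a receptor for the growth factor GDNF (3.09, adjusted p = 0.000566, at least 1.4-fold). They were followed by Marcks, a protein kinase C substrate (2.64, adjusted p = 1.56e-05, with 4.55 at 14 and 0.72 at 21 days), and the stress gene Gadd45a (2.18, adjusted p = 0.000344). Reg3b, a secreted lectin, rose by 2.14 (adjusted p = 0.00131), as Gadd45a did with both groups below background at 1 time or more. Vamp1, a synaptic vesicle protein, had the largest fall and fell by 4.16 (SE 0.36, adjusted p = 2.12e-05), at least 1.08-fold. It was 319.9 ± 51.2 (n = 3) in sham at 21 days and not above background in CCI. Kctd13, an adaptor of a ubiquitin ligase, fell by 2.19 (adjusted p = 8.87e-07), at least 3.20-fold, a mean of -4.20 at 14 days and -0.18 at 21 days. Grhpr, Nptn, Kcns1, Nr3c1, Ntsr2 and Apbb3 fell by 1.80 to 2.58, with adjusted p from 0.000106 to 0.0225, and gave no fold because both groups were below background at 1 time or more. The calls of Nr3c1, Kcns1 and Grhpr were lost in 8, 6 and 4 of 23 alternative settings. With the replicate number as a block the call of Nr3c1 ended (adjusted p = 0.0558, from 0.0152 to 0.178 over its alternative settings). Of the genes always reported, Jun (1.05, adjusted p = 0.126), Sst (-1.73, adjusted p = 0.112), Scn9a (-0.31, adjusted p = 0.306), P2rx3 (-0.37, adjusted p = 0.503) and Tac1 (-0.38, adjusted p = 0.545) did not pass. Neither did Trpv1 (0.29, adjusted p = 0.851), Sprr1a (0.14, adjusted p = 0.907), Calca (-0.06, adjusted p = 1) or Sox11 (-0.05, adjusted p = 1). Marcks has 6 probe sets, of which 1 other shared the direction, and Kctd13 has 3, of which 1 other did. The other probe set of Sst, of Calca and of Scn9a had the opposite sign.

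By group, 10 of the 37 axotomy and regeneration genes measured rose after CCI, 16 when adjusted over the list alone, and none fell (camera adjusted p = 1.46e-15, and 1.54e-05 with an estimated correlation). They included Npy, Gal and Atf3, while Stmn4, a tubulin-binding protein of neurons, had a change of 2.18 that did not pass (adjusted p = 0.198). Of 10 neuropeptides raised by axotomy 4 rose, and 4 when adjusted over the list alone, namely Npy, Gal, Vip and Vgf (1.52, adjusted p = 0.000737). That list shifted up (adjusted p = 5.9e-06, and 0.00266 with an estimated correlation). Among 13 markers of non-peptidergic nociceptors, the small pain-sensing neurons with few neuropeptides, Scn11a, Scn10a and the complement regulator Cd55 (-1.29, adjusted p = 0.024) fell, the call of Cd55 being lost in 8 of 23 alternative settings. When adjusted over the list alone 4 fell and 2 rose, and the list shifted down (adjusted p = 0.00264, and 0.0232 with an estimated correlation). The sodium channel list shifted down with the same Scn10a and Scn11a, 2 of 10 genes and 3 when adjusted over the list alone (adjusted p = 0.0229, but 0.141 with an estimated correlation). Scn1a had a change of -1.27 that did not pass (adjusted p = 0.196).

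Among immune genes, 5 of 23 antigen presentation genes rose after CCI, and 7 when adjusted over the list alone (camera adjusted p = 2.41e-07, and 0.000818 with an estimated correlation). Cd74 on its representative probe set rose by 1.76 (SE 0.14, adjusted p = 1.03e-05), 3.49-fold, and RT1-Da, an MHC class II chain, rose by 1.57 (SE 0.13, adjusted p = 1.56e-05), 3.03-fold. The protease Ctss rose by 1.42 (SE 0.14, adjusted p = 6.99e-05), at least 1.53-fold, and the others were RT1-Bb and RT1-CE12. Of 19 macrophage markers 2 rose, and 3 when adjusted over the list alone, namely Ctss and the lysozyme gene Lyz2 (1.21, adjusted p = 0.00794). The list's call (adjusted p = 0.0229) was lost with an estimated correlation (adjusted p = 0.0659). Of 16 interferon-stimulated genes Ifitm3 alone rose, and 2 when adjusted over the list alone. That list's call (adjusted p = 0.000227) was also lost with an estimated correlation (adjusted p = 0.0586).

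Of 37 ribosomal protein genes 6 rose, and 8 when adjusted over the list alone (camera adjusted p = 2.85e-09, and 0.0232 with an estimated correlation), among them Rpl27 (1.10, adjusted p = 0.000311) and Rpl26 (0.66, adjusted p = 0.0169). The Rpl27 mean joins 2.59 at 14 days to -0.38 at 21 days, with 3 of 6 CCI arrays above the sham mean, and the Rpl26 call was lost in 5 of 23 alternative settings. The oxidative phosphorylation list shifted down (adjusted p = 0.00264, but 0.253 with an estimated correlation). None of its 43 genes fell, and 1 did when adjusted over the list alone, while Cox6c, a subunit of cytochrome c oxidase, rose by 1.90 (adjusted p = 3.14e-06), a mean of 3.53 at 14 days and 0.27 at 21 days. The heat shock list shifted down as well (adjusted p = 0.0229, but 0.287 with an estimated correlation). Of its 23 genes the small chaperone Hspb1 rose (0.88, adjusted p = 0.00209) and the mitochondrial chaperone Hspe1 fell (-0.75, adjusted p = 0.00627, with -1.35 at 14 and -0.14 at 21 days), and 1 rose and 1 fell when adjusted over the list alone. The other 26 lists did not pass, with potassium channels nearest (adjusted p = 0.0591). Among them were the markers of satellite glia, of myelinating and repair Schwann cells, of T, mast and endothelial cells, of neutrophils and of fat.

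In all, 200 probe sets passed for CCI, 104 higher and 96 lower, and 935 had an unadjusted p under 0.05 where 437 are expected by chance. The single-time effects of 160 of the 200 shared 1 sign, and 44 of them were never above background. When the 21-day sham arrays served as control of both CCI groups, a choice made after seeing the data, 86 probe sets passed. The calls of Marcks, Scn10a, Cox6c, Hspb1, Hspe1, Rpl26, Cd55, Nptn and Nr3c1 ended and that of Rpl27 turned to -0.13. Npy, Gal, Atf3, Cacna2d1, Gap43, Scn11a, Cd74, RT1-Da and Ctss stayed past the threshold. With each array centred on its median, 114 passed, 55 higher and 59 lower.

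**Figure D2:**
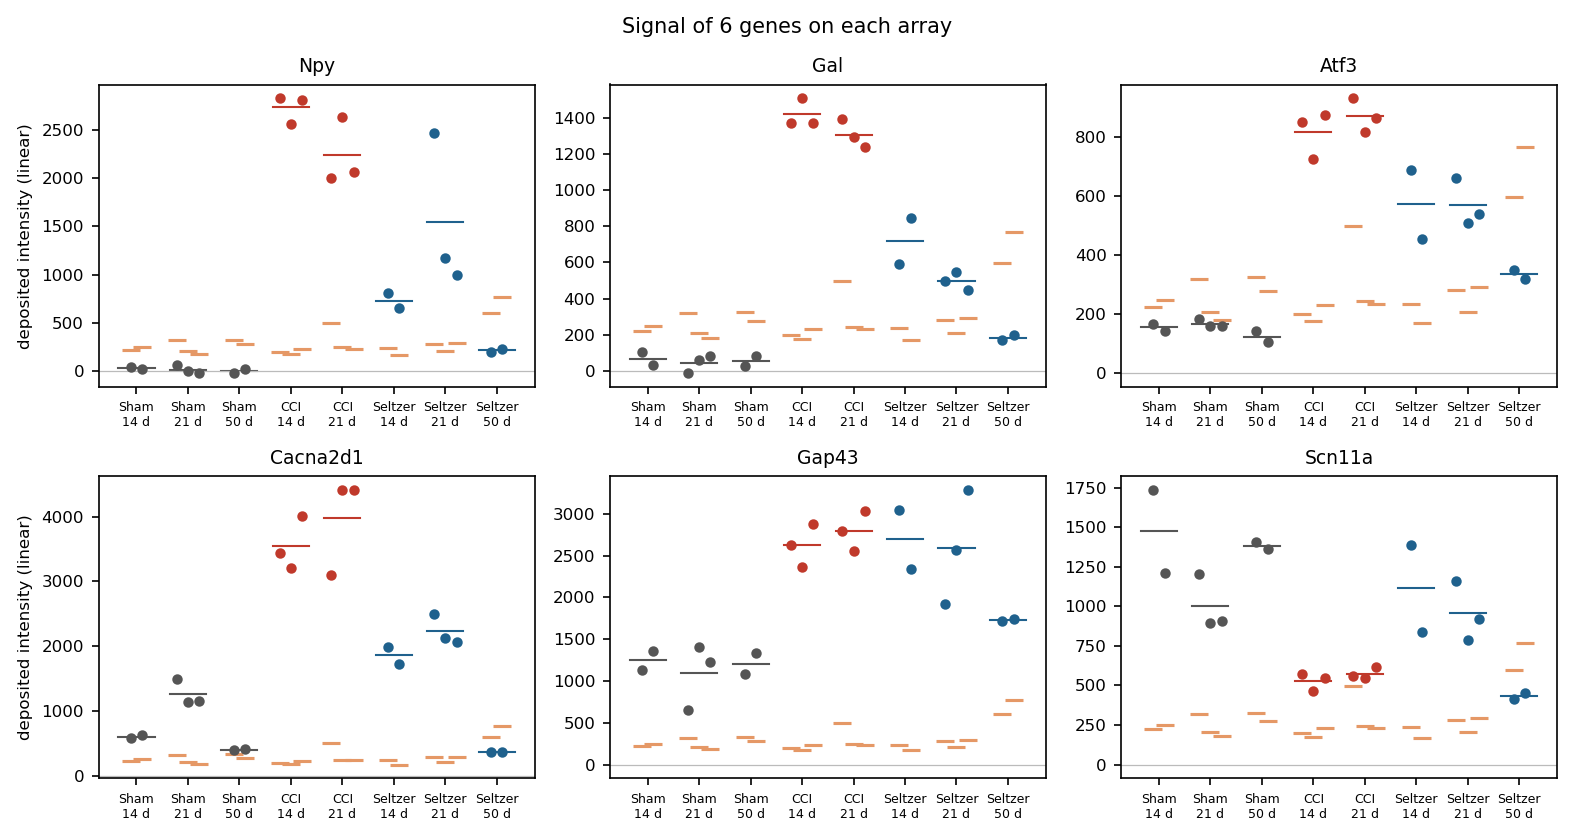
Deposited intensities of genes named for the injury comparisons by group and day, with 1 point per array, bars at group means and dashes at each array's background level. Npy lies at 2733 and 2234 in CCI and at 35.5 and 15.1 in sham on days 14 and 21.

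At 14 days 243 probe sets passed between CCI and sham (118 higher, 125 lower), and at 21 days 81 did (47 higher, 34 lower). At both times 14 were higher, where 0.635 are expected of independent lists, and 9 were lower, where 0.486 are expected. Another 14 passed in opposite directions, 3 higher at 14 and lower at 21 days and 11 the reverse. At 14 days Npy was at least 11.6-fold higher, Gal at least 6.01-fold, Atf3 at least 3.46-fold and Cacna2d1 5.89-fold. At 21 days the folds were at least 9.69, 5.71 and 3.81 for Npy, Gal and Atf3, and 3.13 for Cacna2d1. The size for Cacna2d1 at 14 days depended on the setting. Its log2 change of 2.53 ran from 1.49 to 2.65 over the alternatives, the 21-day sham arrays as control among them. Gap43 rose at 21 days by 1.41 (adjusted p = 0.0168), a call lost in 4 of 17 alternative settings, and its change at 14 days was 1.07 (adjusted p = 0.0685). Skeletal muscle genes moved in opposite directions. At 14 days 3 of 22 were higher, and 6 when adjusted over the list alone (camera adjusted p = 0.000157, and 0.0313 with an estimated correlation). At 21 days 3 of 22 were lower, and 6 when adjusted over the list alone (adjusted p = 0.000114, and 0.0359 with an estimated correlation). Muscle actin, Acta1, was 4080 ± 299 (n = 3) in CCI against 1707 ± 231 (n = 2) in sham at 14 days (adjusted p = 0.00401). At 21 days Acta1 was 450.7 ± 41.0 (n = 3) in CCI against 1642 ± 227 (n = 3) in sham (adjusted p = 0.000184). Without Sham 14-day replicate 1 the 14-day count was 142, and with only the groups compared in the fit the counts were 514 at 14 days and 13 at 21 days.

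After the Seltzer injury the same neuropeptides and Atf3 rose against sham, as means over 14, 21 and 50 days. Npy rose by 4.26 (SE 0.35, adjusted p = 1.42e-05), Gal by 2.73 (SE 0.36, adjusted p = 0.000732) and Atf3 by 1.59 (SE 0.10, adjusted p = 1.28e-06), each on 7 of 7 Seltzer arrays. At 21 days, Npy was 1544 ± 804 (n = 3) against 15.1 ± 41.4 (n = 3) in sham, at least 6.21-fold, Gal at least 2.17-fold (a call lost in 4 of 17 alternative settings) and Atf3 at least 2.48-fold higher. At 50 days all 3 were below background in both groups. Gal did not pass at 14 days (3.22, adjusted p = 0.113) or at 50 days (1.59, adjusted p = 0.131). Cacna2d1 rose by 0.76 (SE 0.098, adjusted p = 0.000525) on average, on 5 of 7 arrays. It showed a 3.08-fold difference at 14 days, 1.77-fold at 21 days and a change of -0.13 at 50 days that did not pass (adjusted p = 0.78). Each day had its own sham arrays, so a difference that changes with the day can come from either group. The 21-day call (0.82, adjusted p = 0.0343) was lost in 10 of 17 alternative settings. Its change ran from 0.71 to 0.94 over them and its adjusted p from 0.00245 to 0.59, with 0.0799 under the replicate block.

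Gap43 rose by 0.96 (adjusted p = 0.00527), 1.96-fold, and Vip rose by 1.66 (adjusted p = 0.00355) below background. Of the other genes with the largest rises, the glycolytic regulator Pfkfb4 (1.83, adjusted p = 0.0101), the transcription factor genes Pax4 (1.80, adjusted p = 0.0349) and Foxa1 (1.58, adjusted p = 0.0387) and Zfp354a (1.58, adjusted p = 0.038) gave no fold, because of values below background. The calls of Pax4, Foxa1 and Zfp354a held in 12, 6 and 9 of 25 alternative settings. With the replicate block those of Foxa1 (adjusted p = 0.053, from 0.00758 to 1 over its settings) and Zfp354a (0.0627, from 0.0105 to 1) ended. The largest falls were those of Napa, a vesicle fusion protein (-2.06, adjusted p = 0.000326), Ndufs8, a subunit of respiratory complex I (-2.04, adjusted p = 0.0293), and Grhpr (-1.91, adjusted p = 0.0293). Next were the acid-sensing channel Asic3 (-1.90, adjusted p = 0.00236), the calcium-binding protein gene Tesc (-1.87, adjusted p = 1.91e-05) and the cell death gene Bad (-1.84, adjusted p = 1.57e-06). Last were the neuropeptide Sst (-1.81, adjusted p = 0.0352, at least 1.54-fold) and the potassium channel subunit Kcns1 (-1.79, adjusted p = 0.00906). Scn11a fell by 0.71 (adjusted p = 0.00762), at least 1.42-fold, and P2rx3, the ATP receptor of nociceptors, by 0.69 (adjusted p = 0.0278), at least 1.41-fold. Of 26 alternative settings the call of Sst was lost in 13, those of Ndufs8 and Grhpr in 10 each and that of P2rx3 in 7. Many of these means rest on 50 days, where the Seltzer arrays had background levels of 599 and 766 and GAPDH ratios of 5.10 and 8.89. At 14, 21 and 50 days in turn the change was 0.23, 0.13 and 5.12 for Pfkfb4, -0.40, -0.82 and -4.97 for Napa, -0.52, -0.23 and -5.36 for Ndufs8, and -0.049, -0.27 and -5.39 for Asic3. It was -0.91, -1.15 and -3.56 for Tesc, -0.081, -0.38 and -5.07 for Bad, and -0.32, -0.25 and -4.87 for Sst. For Scn11a it was -0.42, -0.071 and -1.64, and for P2rx3 -0.33, 0.040 and -1.79. Not past the threshold were Scn10a (-0.28, adjusted p = 0.412), Calca (-0.40, adjusted p = 0.448), Sprr1a (0.22, adjusted p = 0.568) and Jun (0.32, adjusted p = 0.632). The same held for Tac1 (-0.14, adjusted p = 0.794), Scn9a (-0.08, adjusted p = 0.806), Trpv1 (0.17, adjusted p = 0.868) and Sox11 (0.11, adjusted p = 0.962). No other probe set of Napa, Bad, Grhpr, Calca or Scn9a shared its direction, and 1 of 3 others of Ndufs8 did.

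Of the 37 axotomy and regeneration genes 9 rose after the Seltzer injury, and 11 when adjusted over the list alone (camera adjusted p = 5.1e-05, and 0.00522 with an estimated correlation). The neuropeptide list shifted up, with Npy, Gal, Vip, Vgf (0.79, adjusted p = 0.0222, lost in 7 of 26 settings) and Adcyap1 up, 5 of 10 genes and 5 when adjusted over the list alone (adjusted p = 0.000141, and 0.00759 with an estimated correlation). Of 23 antigen presentation genes 5 rose, and 7 when adjusted over the list alone (adjusted p = 0.000235, and 0.00759 with an estimated correlation). They were RT1-Da (1.20, adjusted p = 4.27e-05, 2.33-fold), Ctss (1.13, adjusted p = 0.000128), Cd74 (0.82, adjusted p = 0.00169, with 1.12, 1.65 and -0.30 at 14, 21 and 50 days), RT1-Bb and RT1-CE12. The oxidative phosphorylation list shifted down, with 10 of 43 genes lower and 24 lower and 1 higher when adjusted over the list alone (adjusted p = 8.11e-14, and 0.00981 with an estimated correlation), including Ndufs8 and Cox5b (-0.92, adjusted p = 0.0116, with -0.48, 0.28 and -2.56 at 14, 21 and 50 days). At 50 days 18 of these 43 genes fell, on Seltzer arrays with background levels of 599 and 766. The GAPDH ratios of those arrays, 5.10 and 8.89, rest on middle signals below background. At 14 days 0 fell and at 21 days 0 fell by limma. At these days 330 and 577 of all probe sets had an unadjusted p under 0.05, where 437 are expected by chance.

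Of 16 interferon-stimulated genes 4 rose, Mx1 (0.83, adjusted p = 0.0322), Oas1a (0.53, adjusted p = 0.0366, with -0.24, 0.48 and 1.36 at 14, 21 and 50 days), Ifitm3 and Lgals3bp, and 6 when adjusted over the list alone. The calls of Mx1 and Oas1a were lost in 12 and 14 of 26 alternative settings. The list's call was lost with an estimated correlation (adjusted p = 0.000628, then 0.0813 with an estimated correlation). The call of the immediate early genes was lost too, with Atf3 up, 1 of 21 and 3 when adjusted over the list alone (adjusted p = 0.00627, then 0.0773 with an estimated correlation). The heat shock list, with Hsph1 (-0.96, adjusted p = 0.00981, with -0.66, 0.061 and -2.27 at those days) down, 1 of 23 and 1 when adjusted over the list alone, had adjusted p = 0.00627, then 0.209 with an estimated correlation. The pan-neuronal list shifted down with Elavl4 down and Gap43 up, 1 gene each of 13, and 4 down and 1 up when adjusted over the list alone (adjusted p = 0.0307, then 0.154 with an estimated correlation). Among 13 calcium channel genes Cacna2d1 alone rose, 2 when adjusted over the list alone (adjusted p = 0.0487, then 0.108 with an estimated correlation). With the replicate block the call of the calcium channels list ended (adjusted p = 0.0592, from 0.000151 to 0.162 over its settings). The other 27 lists did not pass, with skeletal muscle nearest (adjusted p = 0.0851).

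In all, 383 probe sets passed for the Seltzer injury, 168 higher and 215 lower, with 1491 at an unadjusted p under 0.05 where 437 are expected by chance, and 93 of the 383 were never above background. With the 50-day arrays left out, a choice made after seeing the data, 21 passed (15 higher, 6 lower), Npy, Gal, Atf3, Cacna2d1, RT1-Da, Ctss and Cd74 among them, and 21 of the 28 named gene results past the threshold no longer passed. Some of these kept changes about as large or larger on the fewer arrays, such as Gap43 (1.18), Vgf (1.24), Vip (1.57) and Grhpr (-2.56). Others came near 0, such as Pfkfb4 (0.18), Asic3 (-0.16), Bad (-0.23), P2rx3 (-0.15), Scn11a (-0.25) and Cox5b (-0.10). Of the 9 lists, the pan-neuronal, calcium channel and heat shock lists also lost their calls, while 8 lists passed in all, so others gained one. Without Seltzer 14-day replicate 2 the count was 247, and with each array centred on its median it was 230, 81 higher and 149 lower. At single times 18 probe sets passed at 14 days (12 higher, 6 lower), 33 at 21 days (23 higher, 10 lower) and 1391 at 50 days (762 higher, 629 lower, 752 of them never above background). Without Seltzer 14-day replicate 1, Sham 14-day replicate 1 or Sham 14-day replicate 2 the 14-day count was 56, 39 or 29. Without Seltzer 21-day replicate 1, 2 or 3 or Sham 21-day replicate 3 the 21-day count was 19, 56, 20 or 21, and without Seltzer 50-day replicate 1 or Sham 50-day replicate 1 or 2 the 50-day count was 790, 799 or 660.

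**Figure D3:**
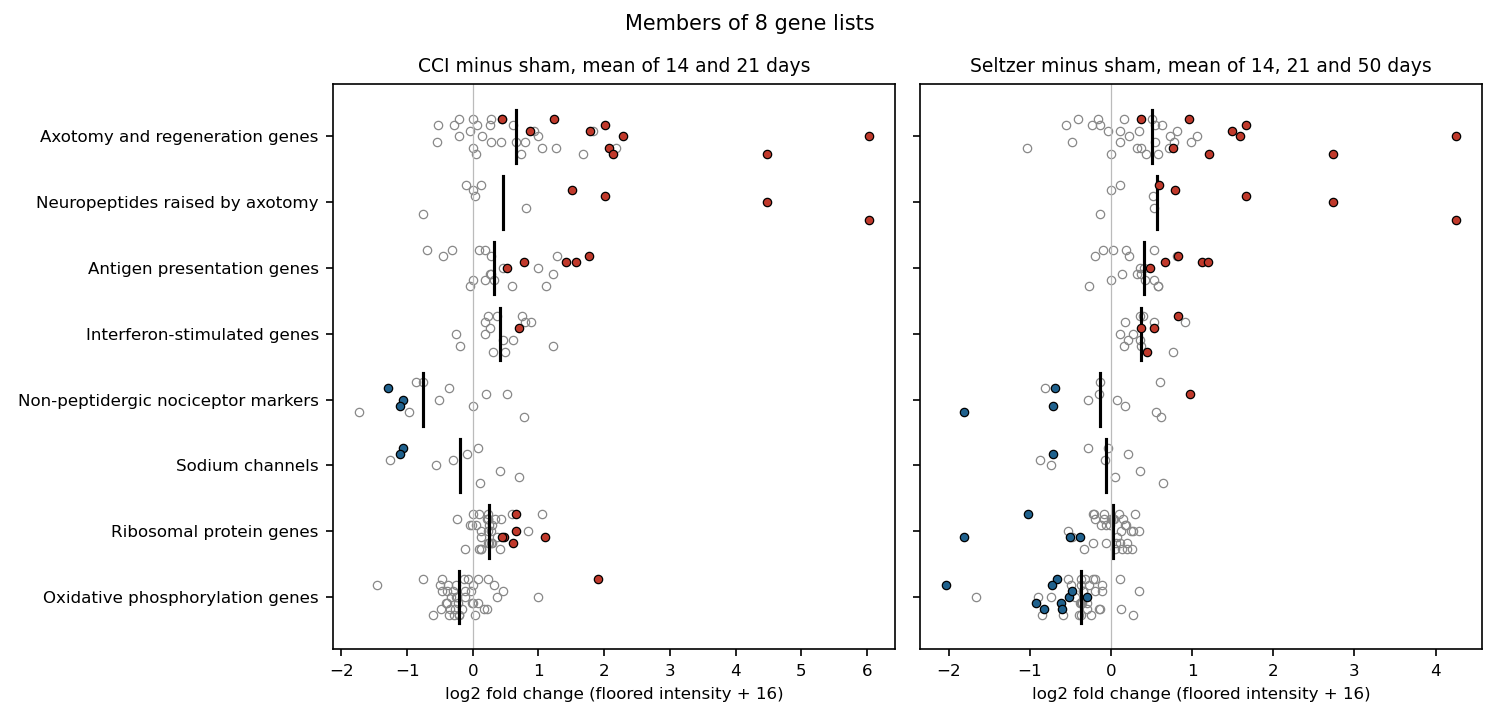
Log2 changes of the members of 8 gene lists against sham, for CCI and for Seltzer, with 1 point per gene, filled where past the threshold, and a vertical bar at each list's median. Of the 37 axotomy and regeneration genes 10 are past the threshold for CCI and 9 for Seltzer, all to the right of 0.

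Set directly against each other at 14 and 21 days, CCI ganglia had more Cacna2d1 mRNA than Seltzer ganglia, by 0.87 (SE 0.11, adjusted p = 0.00093), 1.84-fold and on 6 of 6 arrays. They also had more Atf3, by 0.57 (SE 0.11, adjusted p = 0.033), 1.5-fold, a call lost in 11 of 23 alternative settings (changes from 0.42 to 0.71, adjusted p from 0.00407 to 0.265). Scn11a was lower in CCI (-0.86, SE 0.15, adjusted p = 0.0118), 1.84-fold. For Npy (1.26, SE 0.40, adjusted p = 0.256), Gal (1.18, SE 0.41, adjusted p = 0.327) and Scn10a (-0.72, SE 0.18, adjusted p = 0.088) the difference between the models did not pass. Nor did it for Vip, Gap43, Jun, Sox11, Sprr1a, Tac1, Calca, Sst, P2rx3, Trpv1 and Scn9a, with changes from -1.45 (Sst) to 0.44 (Vip) and adjusted p from 0.254 (Scn9a) to 1.

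The largest differences upward in CCI were those of the G protein subunit Gnb1 (2.44, SE 0.17, adjusted p = 7.03e-06, at least 3.83-fold), Marcks (2.20, adjusted p = 0.000146, at least 3.33-fold) and the proteasome subunit Psmb4 (1.26, adjusted p = 0.00155). Smaller ones were those of the prostaglandin D synthase Ptgds (1.03, adjusted p = 0.0262), Dpysl2, which acts in axon growth (1.00, adjusted p = 0.00264), the matrix protein Sparc (0.94, adjusted p = 0.00015) and Rps29 (0.92, adjusted p = 0.00294). Downward they were those of Vamp1 (-2.54, adjusted p = 0.0025), Actr2 (-1.93, adjusted p = 0.0283), Sart1 (-1.75, adjusted p = 0.000689) and Tmtc3 (-1.60, adjusted p = 0.000132). They were followed by Ivd (-1.43, adjusted p = 3.67e-06), the GDNF receptor tyrosine kinase Ret (-1.13, adjusted p = 0.0142), Hgs (-1.08, adjusted p = 0.00288) and Rfk (-1.06, adjusted p = 0.0435). The calls of Actr2, Rfk and Ptgds were lost in 13, 11 and 10 of 23 alternative settings. Gnb1 was 2710 ± 180 (n = 3) in CCI at 14 days, 84.4 ± 1.79 (n = 2) in Seltzer and 112.8 ± 74.5 (n = 2) in sham at 14 days. At 21 days it was 2735 ± 523, 2492 ± 161 and 3309 ± 192 (n = 3 each) in the same order. The low values were thus those of both the Seltzer and the sham arrays at 14 days. Whether a difference between sets of arrays accounts for this or other calls between the models was not tested on those calls. It may account for many of the 243 calls between CCI and sham at 14 days. Their change followed the Seltzer change from 14 to 21 days (r = 0.668). No other probe set of Marcks, Dpysl2, Sart1 or Sst shared its direction, and 1 of 2 others did for each of Gnb1, Ivd and Ret.

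Of 37 axotomy and regeneration genes 4 were higher in CCI, Atf3, Hspb1, Timp1 and Cacna2d1, and 4 when adjusted over the list alone (camera adjusted p = 3.16e-05, and 0.00435 with an estimated correlation). The ribosomal list was shifted up, with Rpl27 (1.41, adjusted p = 7.22e-05) and Rps16 past the threshold of 37 and 10 up and 1 down when adjusted over the list alone (adjusted p = 1.64e-08, and 0.0344 with an estimated correlation). The non-peptidergic nociceptor list was shifted down, with Scn11a as 1 of 13 and 4 when adjusted over the list alone (adjusted p = 0.00129, and 0.0269 with an estimated correlation). The antigen presentation list was shifted up with 0 of 23 members past the threshold by limma over all probe sets and 0 when adjusted over the list alone (adjusted p = 0.0109, and 0.0344 with an estimated correlation). The sodium channel list was shifted down with Scn11a, 1 of 10, and 3 down and 1 up when adjusted over the list alone (adjusted p = 0.0443, but 0.277 with an estimated correlation). With the replicate block the call of the sodium channels list ended (adjusted p = 0.0871, from 0.0132 to 0.802 over its settings). The other 31 lists did not pass.

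In all, 81 probe sets passed between the models, 42 higher and 39 lower in CCI, 12 of them never above background. With the 14-day arrays left out of the contrast, a choice made after seeing the data, 10 passed (2 higher, 8 lower), none of the 19 named gene results past the threshold stayed past it, and Rpl27 turned to -0.21. On those fewer arrays the differences of Cacna2d1 (0.82), Vamp1 (-2.68), Ret (-1.48), Hgs (-1.18) and Atf3 (0.61) kept about their size or grew. Those of Gnb1 (0.12), Psmb4 (0.029), Dpysl2 (0.0050) and Sparc (0.090) came near 0, and Sart1 and Ivd did not differ. Of the 5 lists the axotomy list alone kept its call, while 4 lists passed in all, so others gained one. Without CCI 21-day replicate 1 the count was 152, and with each array centred on its median it was 43.

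Among the probe sets past the threshold for each model against sham, 33 were higher in both, where 2.00 are expected of independent lists, and 34 lower in both, where 2.36 are expected, 10 were higher in CCI and lower in Seltzer, and 2 the reverse. The 14- and 21-day sham arrays were shared, which alone makes lists overlap. In unchanged groups simulated 100 times against the same sham arrays a mean of 0.01 probe sets passed as higher in both and 0 as lower. When as many probe sets were taken from the top of each simulated list as had passed, 21.9 were higher in both (at most 32), 24.0 lower in both (at most 36) and 0.66 opposite (at most 3), against the 12 observed as opposite. With these sham arrays split between the models, over 12 splits, 19.7 passed as higher in both (13 to 30), 24.7 as lower (14 to 36) and 10.3 in opposite directions (4 to 24). Pearson's r of the 2 models' changes across 8740 probe sets, over 14 and 21 days, was 0.509. Unchanged groups simulated 100 times against the same sham arrays gave a mean r of 0.529, with a covariance of 0.0892 against 0.0943 observed. With the sham arrays split between the models, each part keeping at least 2, r averaged 0.0679 over 12 splits, from -0.0243 to 0.127. Probe sets are not independent replicates, so no p-value is given for r.

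Over time, the CCI effect differed between 14 and 21 days for 157 probe sets (80 with a positive and 77 with a negative difference of the effect at 21 minus 14 days), 33 of them never above background. The Seltzer effect differed over 14, 21 and 50 days for 536 probe sets in an F test with 2 degrees of freedom, of which 156 were never above background. The genes with the smallest adjusted p were Cdh16 (5.78e-12), Avpr1a (6.38e-09), Akp3 (1.68e-08), Star (1.94e-08) and Ssr3 (9.45e-08). In sham ganglia 741 probe sets differed between days, 206 of them never above background. The sham 50-day arrays had GAPDH ratios of 2.84 and 2.85, against 0.998 to 2.04 on all 14- and 21-day arrays. The middle signals were 543 and 519 against 1276 to 4526, so these signs of RNA quality moved with the day. The actin 3' to 5' ratios of sham did not. They were 2.35 and 1.66 at 50 days, 2.40 and 2.38 at 14 days and 1.30 to 1.85 at 21 days. The 741 were led by Akp3 (8.76e-10), Ssr3 (3.79e-09), Map1b (1.37e-08), Ivd (1.47e-08) and Gnb1 (4.15e-08). Of these, Gnb1 on its probe set U88324_at was 147.8 ± 42.2 (n = 2) at 14 days, 1708 ± 125 (n = 3) at 21 days and 1310 ± 136 (n = 2) at 50 days in sham. Its day apart was thus day 14, when the sham GAPDH ratios were 1.90 and 1.74, so it does not follow the 50-day signs of RNA quality. What sets the 14-day sham arrays apart for it was not tested. Without Sham 50-day replicate 1 or 2 the sham count was 442 or 462, and the Seltzer count 350 or 316.

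**Figure D4:**
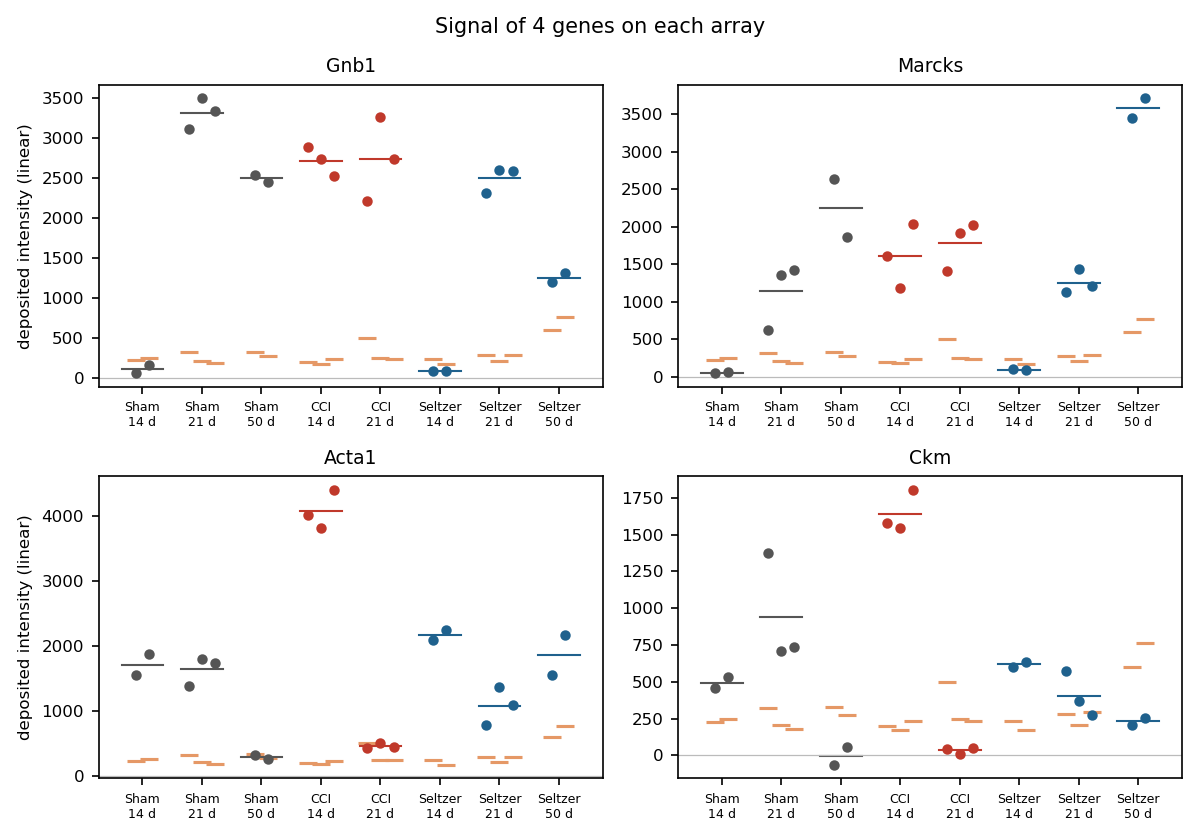
Deposited intensities of Gnb1, Marcks, Acta1 and Ckm by group and day, with 1 point per array, bars at group means and dashes at each array's background level. Gnb1 lies at 112.8 in sham and 84.4 in Seltzer at 14 days, and at 2710 in CCI.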

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

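The tests of RNA degradation and of muscle tissue below were chosen only after the result was seen. Effects that differed between days by a test of the difference itself are given first. The CCI effect differed between 14 and 21 days for 157 probe sets, and the Seltzer effect over 14, 21 and 50 days for 536. At 21 minus 14 days the CCI effect differed by -3.84 on the log2 scale for Marcks, -3.25 for Cox6c, -2.97 for Rpl27, 4.02 for Kctd13 and 1.21 for Hspe1. By list it differed for skeletal muscle (adjusted p = 3.85e-07, and 0.0224 with an estimated correlation), myelinating Schwann cells (0.00296 and 0.0453), and, with calls that an estimated correlation ended, ribosomal proteins (6.93e-05, then 0.149), oxidative phosphorylation (0.000419, then 0.277), sodium channels (0.00578, then 0.133) and extracellular matrix (0.0436, then 0.105).

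The Seltzer effect differed over the 3 days for Pfkfb4 (adjusted p = 0.00516), Napa (0.00126), Ndufs8 (0.0272), Asic3 (0.00107), Tesc (0.00267), Bad (6.81e-07), Sst (0.0288), Cacna2d1 (0.00368), P2rx3 (0.0253), Scn11a (0.0207), Cd74 (0.00361), Oas1a (0.0316), Cox5b (0.0042) and Hsph1 (0.0157). The GAPDH control probe sets, outside the gene comparisons, had 3' to middle ratios of 5.10 and 8.89 on the Seltzer 50-day arrays against at most 2.85 elsewhere. The middle signals of those 50-day arrays, 198 and 120, lay below background.

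At 14 days 243 probe sets differed between CCI and sham. Over them, the change followed the Seltzer change from 14 to 21 days, which shares no array with it (r = 0.668, the same sign for 188 of 243). A difference between sets of arrays, which the labels do not name, may therefore account for many of these calls. The 7 called axotomy genes argue against it for themselves, since their median Seltzer change was 0.26, below 1.14, the bound set from their median CCI change of 2.28, by more than 2 standard errors (0.35). The r of the 243 with the CCI change at 21 days was 0.172, below the bound set as arguing against an injury effect common to both days. Noise also lowers r, and the 21-day group holds the noisy CCI replicate 1, so r cannot exclude such an effect. Of the 243, 23 passed in the same direction on both days and 14 in opposite directions. An injury effect particular to 14 days stays open and was not tested.

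At 50 days 1391 probe sets differed between Seltzer and sham. Over them, r with the mean Seltzer change at 14 and 21 days was 0.0958, below the bound set as arguing against a shared effect. Noise also lowers r, so it cannot exclude a shared effect. Of the 1391, 752 were never above background, and 18 and 33 probe sets passed at 14 and 21 days. Some single genes did pass again. Of the 21-day calls 11 of 23 higher (2.01 expected of independent lists) and 4 of 10 lower (0.720) passed again in the same direction, and 3 in the opposite one. Of the 14-day calls 4 of 12 higher (1.05) and 1 of 6 lower (0.432) did, and 1 in the opposite one. Atf3 (1.75, 1.67 and 1.34) and Npy (3.88, 5.67 and 3.22) passed on all 3 days, but at 50 days both were below background in both groups. The Npy call was lost in 6 of 14 alternative settings at 14 days and in 3 of 14 at 50 days. Its 50-day change ran from 0.11 to 5.47 over them. Both 50-day calls were lost with only the groups compared. Degraded or incompletely copied RNA may account for calls, and the lower of both Seltzer 50-day GAPDH ratios, 5.10, exceeded every other array's. These ratios cannot tell it from array quality, because the middle signals under them (198 and 120) lie below those arrays' background levels (599 and 766). The other control signals pointed both ways. The GAPDH 3' signals (1011 and 1066) lay close to the 5' signals (781 and 920), unlike in sham at 50 days (1543 and 1480 against 438 and 505). The actin 3' to 5' ratios, 3.94 and 9.88, exceeded every other array's. Array quality and an effect of the injury at 50 days cannot be told apart, because both 50-day Seltzer arrays have high background, and the r of 0.479 with the noisy CCI 21-day replicate 1 lay between the bounds set for it. A late injury effect stays open as untested.

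Skeletal muscle genes were higher in CCI at 14 days and lower at 21 days. A difference between the 14- and 21-day arrays of every group is argued against. From 14 to 21 days the list's median changed by 0.000516 in sham and -0.59 in Seltzer against -0.86 in CCI. The sham value lies off the bound set from the CCI change (-0.43) by more than 2 standard errors (0.38), while the Seltzer value met it. A set of arrays joining CCI at 14 days to the 21-day arrays was not tested by this. Differing amounts of muscle carried along with the ganglion may account for it, but the test of it rests on few genes. It also uses the CCI and sham arrays that gave the pattern, so it largely restates the pattern and cannot decide. Of the members above background on every 14- and 21-day Seltzer array, a choice that uses neither group compared, 3 of 3 were higher in CCI at 14 days and 3 of 3 lower at 21 days (100%). Of the 19 others 14 were higher and 11 lower. This choice took the place of one made on the compared arrays, which favoured the direction found. The brightest, Acta1, lay at 4080 and 450.7 in CCI and at 1707 and 1642 in sham. Of 22 members measured, 5 were above background on every 14- and 21-day sham array and 1 is in another list, and a change of these genes within the ganglion stays open.

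Other groupings of the same arrays were tried, with 100 drawn where there were more, and the numbers as large count the real grouping. A share under 0.05 was set beforehand as arguing against chance. The CCI mean met this (200 probe sets, highest other 165, 1 of 100 groupings as large, and 10 lists, highest other 8). So did the Seltzer mean (383, highest other 373, and 9 lists, highest other 9, 2 of 100 as large). The grouping with 373 exchanged both 50-day groups, so the count does not tell injury from the quality of the 50-day arrays. CCI against Seltzer did not meet it (81, highest other 125, 6 of 100 as large), but its 5 lists did (highest other 6, 4 of 100 as large). The grouping with 125 kept the 14-day labels and exchanged those of 21 days. The shares were not corrected for the number of tests, and these groupings ignored the replicate pairs. They cannot exclude a difference between sets of arrays that goes with the groups. At 21 days alone the 10 groupings are too few for a share under 0.05, with 81 for CCI and a highest other of 12, and 33 for Seltzer and a highest other of 83. The grouping with 83 put Seltzer replicates 1 and 3 with sham replicate 1, so it parted 1 of the 3 replicate pairs and kept 2 together. The other 5 groupings that do so gave 0 to 2, so keeping pairs together does not by itself explain the 83. The real grouping parts all 3 pairs, and the other 3 groupings that do gave 0. With the replicate block 24 probe sets passed in place of 33. That block is common to all groups and days, and no test within the 21-day pairs alone was run.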

How the results depend on the processing

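A floor at 200, the 21-day replicate 1 arrays left out together, the 50-day arrays left out, the 21-day sham arrays as common control and the 14-day arrays left out were chosen only after the result was seen. The counts of probe sets stayed within 1.5 times their value with a pseudocount of 1 or 64, quantile normalization, eBayes with trend, and the replicate block. With the block 24 passed for Seltzer at 21 days, 97 of 101 named gene results past the threshold stayed past it, and 4 did not, namely Nr3c1, Foxa1, Zfp354a and Cacna2d1 for Seltzer at 21 days. The sodium channel list of CCI against Seltzer and the calcium channel list of Seltzer also lost their calls with it. No other call changed among the named gene and list results tried with it, while 177 probe sets passed for CCI in place of 200. Calls of lists and named genes for an effect over time were not tried with it. Of the 101, 28 lost their call with only the groups compared, 26 with the floor at 200, 17 with arrays centred, 14 with a pseudocount of 1 and 6 with quantile normalization. With a pseudocount of 64 and with array weights 1 did, and with trend 0. With the dimmest probe sets left out 5 of 94 did, without the 21-day replicate 1 arrays 3 of 90, and with 1 array left out 149 of 1069. Without the 50-day arrays 21 of 28 did, with the 21-day sham arrays 11 of 38 lost or turned, and without the 14-day arrays 19 of 19. Npy, Gal, Atf3, Cacna2d1, Gap43, Scn11a, Vgf, Ctss, Cd74, RT1-Da, Gfra1, Vamp1 and Kctd13 passed in every alternative tried for the CCI mean. For the Seltzer mean Npy, Gal, Atf3, Cacna2d1, RT1-Da and Ctss did. Passing each time does not make an effect common to both days, since Kctd13 changed by -4.20 at 14 and -0.18 at 21 days.

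The cause of the following changes was not tested unless fewer probe sets are named. With arrays centred on their median, 114 probe sets (55 higher, 59 lower) passed for CCI, 230 (81, 149) for Seltzer, and 146 (83, 63) for CCI at 14 days. There were 5 and 9 (8, 1) for Seltzer at 14 and 21 days, 43 (17, 26) for CCI against Seltzer and 91 (33, 58) for the CCI effect over time. There were 1206 (431, 775) for Seltzer at 50 days. Centring moved the median of all changes by 0.123 for CCI at 14 days, -0.167 at 21 days, -0.339 for Seltzer at 50 days and -0.29 for the CCI effect over time. With the dimmest 33.3% of probe sets left out, hence fewer probe sets tested, the counts were 130, 252, 155, 7, 9 and 49 for the same results up to CCI against Seltzer, and 326 for Seltzer over time.

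With array weights they were 518 for CCI, 871 for Seltzer, 784 and 136 for CCI at 14 and 21 days, and 66 and 51 for Seltzer at 14 and 21 days. They were 309 for CCI against Seltzer, 344 for the CCI effect over time, 959 for Seltzer and 1748 for sham over time. With only the groups compared, which changes both the number of arrays and the estimate of the spread, they were 514 and 13 for CCI at 14 and 21 days. They were 0, 0 and 841 for Seltzer at 14, 21 and 50 days by limma, where 752, 461 and 2523 had an unadjusted p under 0.05. With an estimated correlation 5 lists passed for CCI and 4 for Seltzer, and with fry 17 for Seltzer. The correlation of both models' effects was 0.068 with the sham arrays split.

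With values floored at 200, the counts were 621 (455, 166) for Seltzer, 36 (17, 19) and 21 (14, 7) for Seltzer at 14 and 21 days, 1235 (882, 353) at 50 days, 132 (49, 83) for CCI against Seltzer with 9 lists. Without the 21-day replicate 1 arrays they were 394 for CCI, 1039 for Seltzer, 278 for CCI against Seltzer with 2 lists, 257 for the CCI effect over time, 1300 for Seltzer and 1394 for sham over time. Without the 50-day arrays 21 passed for Seltzer. With the 21-day sham arrays as control 86 passed for CCI and 58 for CCI at 14 days. Without the 14-day arrays 10 passed for CCI against Seltzer.

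Direction turned for genes near 0 in the CCI mean, none past the threshold. Sox11 turned to 0.010 with quantile normalization and ran from -0.22 to 0.053 when an array was left out, and Calca ran from -0.29 to 0.060. Trpv1 turned to -0.025 with the floor and ran from -0.011 without Sham 21-day replicate 3 to 0.52. Sprr1a turned to -0.072 with the 21-day sham arrays. Past it before, Rpl27 turned to -0.13 for CCI with those arrays and to -0.21 for CCI against Seltzer without the 14-day arrays.

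Leaving out 1 array at a time gave 147 to 264 for CCI with 8 to 11 lists, 247 (without Seltzer 14-day replicate 2) to 445 for Seltzer with 7 to 10 lists. It gave 142 (without Sham 14-day replicate 1) to 193 and 57 to 99 for CCI at 14 and 21 days. It gave 62 to 152 (without CCI 21-day replicate 1) for CCI against Seltzer with 3 (without CCI 21-day replicate 2) to 5 lists. For Seltzer at 14 days it gave 16 to 56 (without Seltzer replicate 1), with 39 and 29 without Sham replicates 1 and 2. At 21 days it gave 19 (without Seltzer replicate 1) to 56 (replicate 2), with 20 without Seltzer replicate 3 and 21 without Sham replicate 3. At 50 days it gave 660 (without Sham replicate 2) to 984, with 799 without Sham replicate 1 and 790 without Seltzer replicate 1. It gave 118 to 177 for the CCI effect over time, 316 to 597 for Seltzer over time (350 and 316 without Sham 50-day replicates 1 and 2), 442 to 760 for sham over time (442 and 462 without them), and 0.451 to 0.587 for the correlation.

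Signal over background limits what could be seen. In simulated data, 51.8%, 64.5% and 56.2% of 2-fold changes above the median background level were called for CCI, Seltzer and CCI against Seltzer, and 7.53%, 11.4% and 9.54% below it. Of all calls 13.7%, 14.4% and 13.4% were false, 37.4%, 39.6% and 37.6% below that level and 3.22%, 2.35% and 2.65% above it.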
